A study of Mus musculus with 20 samples.

How the data were processed

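Tail DNA of a sire, a dam and 8 offspring was hybridised against 1 reference male on 2-colour oligonucleotide arrays, with the dyes turned between the 2 arrays of an animal, per the labels. Spot intensity in each channel was background-subtracted, spatially detrended and dye-normalised with linear factors by Agilent Feature Extraction 10.7.1.1, per the file headers, and probes were placed on mm9. The intensity medians of spots and local background are also in the deposited scanner files. The log10 ratio of red over green in the scanner files was computed by Feature Extraction from the processed signals, per the file headers, and was used only to check them. The deposited value table holds log2 ratios; set against the scanner values it was log2 of reference over animal, and what further adjustment the authors made to it is not given in the sources used here. Its columns had medians between -0.00631 and 0.0179. The table was used as an alternative only. For offspring 4 the scanner file of 1 orientation was used, and the table gives 643087 values for its other array.

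From the processed signals, log2 of animal over reference was taken by the dyes in the labels, outlier-flagged and control spots were left out, spots of a probe were averaged and each array was centred on its autosomal median, with no loess. The arrays of an animal were averaged to 1 value. For offspring 4 the mean dye effect of the other animals, with an SD of 0.12 on the log2 scale, was removed. Runs of 5 to 1000 probes were scored as the sum of log2 ratios over noise times the root of the number of probes. A call needed a score of 8, a mean of 0.25 and, in each orientation, a mean on the same side of at least 0.5 times that size. Offspring 4, with 1 orientation, could not be held to the last criterion. Calls of one sign sharing at least 0.5 of the shorter one were merged, and an animal carried a region where its mean was at least 0.25 in the region's direction. Tested on simulated data over 950622 probes, the scan recovered 100% of planted changes of -1 over 5 probes at the lowest and highest probe noise. Of changes of 0.4 over 5 probes it recovered 84.6% at the lowest noise and 0% at the highest. It made 0 false calls in simulated Gaussian noise, which lacks the single-probe deviations of the measured arrays.

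Windows of 50 kb with at least 3 probes were tested with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. The plan named genes, but the files pair no probe with a gene and the gene table at hand is on another build, so windows stood in for genes and the fixed gene lists were not tested. The plan also named a trended prior variance. Few windows had an offspring mean of at least 0.25 in size. Among these, the window of chromosome 4 from 78450001 had an SD of 0.044 over the offspring and the others had 0.165 to 0.449. In these windows the trended prior SD ran from 0.382 to 27.4, where the constant prior SD was 0.0327. Why the trended prior rose so far there was not tested. On simulated windows the trended fit recovered 100% of each planted size against the reference. Against the parents it recovered 0% of changes of 0.58 and 82% of changes of -1, where the constant prior recovered 100% of each. False calls in 10 simulated rounds were 0 against the reference with either prior, and 7 with the trended and 10 with the constant prior against the parents. Changes were also added to all 8 offspring at once, in measured windows with small ratios in every animal. Of changes of 0.4, 0.58 and -1 the trended fit recovered 0%, 0% and 8% against the reference, and of -0.4 it recovered 100%. The planned fit is reported as planned, with a constant prior, chosen after the data were seen, beside it.

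The planned tests, thresholds and alternatives and the rule for named regions were set before the data were examined. The windows in place of genes, the constant prior, the random scan-day block against the parents, scan days 2, 4 and 5 alone, the count without regions parting the scan days, the settings without 1 probe and the calls and regions without an animal were added afterwards. The rule took the 15 highest-scoring regions and the 10 highest-scoring of those carried by an offspring and neither parent; windows would have been named by size past the threshold. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. The alternatives were other signals, scores, probe minimums, centring, spot filters and animals left out. The number of arrays limits the precision, and p-values rest on the animals of 1 family.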

Results

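Tail DNA of 1 mouse family was measured by array comparative genomic hybridisation, in which an animal's DNA and a reference DNA carry different dyes and compete for the same probes. The family held a sire, a dam and 8 offspring, and the reference was 1 male of the same colony. The title of the series speaks of males exposed to gamma rays at 1 mGy per day for 400 days, whereas its design text calls the male of this family unexposed, so the exposure of the sire is left open here. No unexposed family was analysed here, and no value below separates exposure from ordinary inheritance. Each animal was hybridised on a pair of arrays with the dyes turned, giving 20 arrays, and scanner files of 19 were used. The 950622 autosomal probes had a median spacing of 2053 bp on build mm9. Probe noise of the animal means ran from 0.10 in offspring 2 to 0.16 in offspring 4 on the log2 scale. All ratios are animal over reference, and each standard error is over the probes of a region in 1 animal, which are not biological replicates.

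The X and Y chromosomes gave the ratios that the labelled sexes of the parents call for against a male reference. The dam had a median log2 ratio of 0.97 over 68 X probes and of -2.22 over 23 Y probes. The sire had 0.01 and 0.02 over the same probes. Offspring 1 to 4 had X ratios of -0.03, 0.02, -0.02 and 0.00, and offspring 5 to 8 had 0.97, 0.90, 0.97 and 0.92. The Y ratios were 0.02, -0.03, -0.02 and 0.17 in offspring 1 to 4. In offspring 5 to 8 they were -2.85, -2.25, -2.78 and -1.46. These are values of single animals and were not tested.

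Copy number differences from the reference were sought along the autosomes of each animal. The 8 offspring gave 157 calls and the sire and dam gave 32, which merged into 121 distinct regions, 88 with a higher and 33 with a lower ratio. Calls were unevenly spread, with 60 in offspring 6 and 32 in offspring 5 against 3 in offspring 4 and 7 in offspring 3. The difference between the turned arrays of an animal, in which copy number cancels, gave 69 calls over 9 animals, 45 of them in offspring 1 and 10 in the sire, against 17 and 13 calls of the ratio itself. The orientation criterion could not apply to that difference. Without the criterion the ratio gave 170 calls in the offspring and 34 in the parents. Many short calls rested on 1 probe. With the most extreme probe of each call left out, a criterion added after the data were seen, 86 of the 189 calls, 35 regions and 2 of the background calls kept a mean of at least 0.25 in size. No region was carried by all 10 animals.

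**Figure D1:**
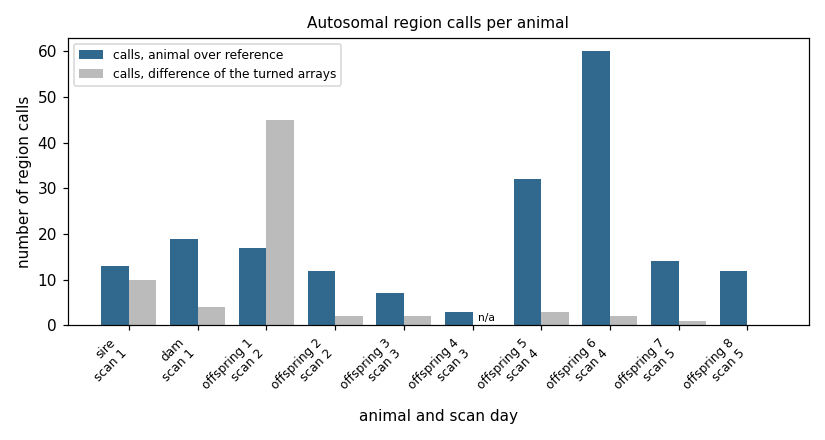
Number of autosomal region calls (vertical axis) in each animal, with its scan day. Blue bars are calls of the animal over the reference and grey bars are calls in the difference of its turned arrays (n/a, offspring 4, with 1 scanner file). The orientation criterion held for the blue bars only. Offspring 6 has 60 calls, and the grey bar of offspring 1, at 45, exceeds its 17 calls.

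The question of which changes came from a parent was addressed by reading every animal over the same regions. The region of chromosome 4 from 78453216 to 78509511, with 18 probes, was lower in the sire at -1.01 ± 0.03 (SE) and lower in all 8 offspring at -0.40 ± 0.04 (SD, n = 8), while the dam had -0.02. A region of chromosome 4 from 101110482 to 101270535, with 74 probes, had 0.58 ± 0.02 (SE) in the dam, 0.56 in offspring 2 and 0.55 in offspring 3 and 6, and lay between -0.02 and 0.03 in the other animals. On chromosome 11, from 47635076 to 47660892, the sire had -0.94 and offspring 5 and 7 had -0.93 and -0.94. The highest-scoring region, on chromosome 2 from 70077520 to 70085630 with 5 probes, had 3.36 in the sire and between 2.90 and 3.88 in offspring 1, 2, 3, 5 and 7. Offspring 6 passed the carrier threshold there at 0.30, and offspring 4 and 8 had -0.24 and 0.19. The size of these ratios is not settled, because 4 of the 5 probes were not well above background on at least 1 array: offspring 5 had 3.88 as reported, 0.61 with normexp, and 0.17, under the carrier threshold, over the probe left without dim probes. On chromosome 2 from 174850105 to 177826783, 20 probes had 0.36 in the sire and between 0.30 and 0.42 in 6 offspring. These probes span 2976.68 kb, on a chromosome with a median spacing of 2138 bp, so most of that interval was not measured.

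The dam carried further regions. On chromosome 3 from 25417435 to 25446265, 5 probes had -1.26 ± 0.38 (SE) in the dam and between -1.24 and -1.02 in offspring 5 to 8, against -0.04 to 0.07 in the other animals. On chromosome 8 from 102122727 to 102253497, 47 probes had 0.26 ± 0.02 (SE) in the dam and 0.28, 0.25, 0.23 and 0.28 in offspring 5 to 8, of which 5 and 8 were read as carriers. The dam and offspring 5 to 8 were also the animals with an X log2 ratio of at least 0.90. Their Y log2 ratios were -1.46 or lower. The region of chromosome 3 was lower in these animals, as the Y was, and that of chromosome 8 was higher, as the X was. For a single region, transmission from the dam cannot be told apart from sequence shared with a sex chromosome. Exactly this set of carriers in 5 regions on 4 chromosomes argues against independent transmission of those regions. That test was chosen after the data were seen. The region of chromosome 6 from 104238274 to 104248165 had -0.73 ± 0.76 (SE) in the dam and -0.82 in offspring 6, and without its most extreme probe offspring 6 had -0.03. A pair of regions on chromosome 3 from 132542035 to 132549490 and from 132548028 to 132556195 likewise had -0.09 in offspring 5 and -0.04 in offspring 6 without that probe. Further regions named by the rule had no parental carrier. On chromosome 11 from 3031505 to 3098381, offspring 5 and 8 had 0.28 and 0.27, and with the running median removed offspring 5 had -0.024. The region begins at the first probe of the chromosome, where the running median was padded with copies of that probe's value. The -0.024 is therefore no test of the region. The others, on chromosome 1 from 48266126, chromosome 3 from 17456923, chromosome 10 from 52268364 and chromosome 13 from 84134525, had 0.51, 0.46, 0.50 and 0.49 in offspring 6, 6, 5 and 5, and 0.06, 0.28, 0.09 and 0.27 without their most extreme probe. With normexp the regions of chromosomes 1, 3, 10 and 13 had 0.13, 0.29, 0.08 and 0.25. With the processed signals that of chromosome 13 had 0.66 in offspring 5 on the array with the animal in Cy3 and 0.33 in Cy5.

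**Figure D2:**
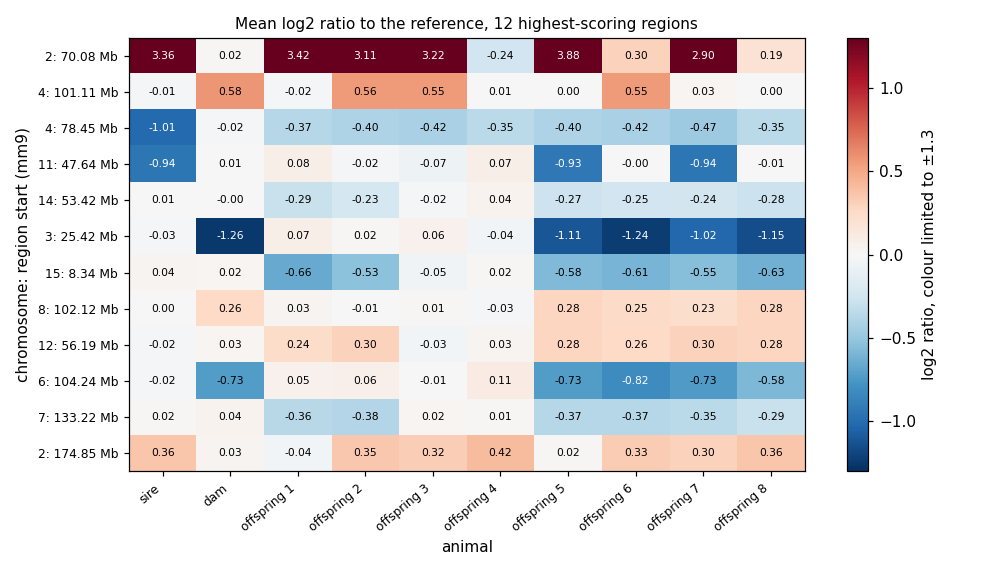
Mean log2 ratio to the reference of the 10 animals (horizontal axis) over the 12 highest-scoring autosomal regions (vertical axis, chromosome and start on mm9), with the value printed in each cell and colour limited beyond 1.3. The region of chromosome 4 near 78 Mb has -1.01 in the sire and negative values in all 8 offspring.

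Of the regions, 34 were carried by exactly 1 parent. The exact two-sided binomial test against a share of 0.5 gave p = 0.00781 for the region of chromosome 4 near 78 Mb, carried by 8 of 8 offspring, and the same p for each of 12 regions carried by 0 of 8. It gave p = 0.727 for the region near 101 Mb, carried by 3 of 8, and p = 0.289 for the region of chromosome 11, carried by 2 of 8. Taking the highest-scoring region of each of 14 chromosomes, 33 of 112 readings were carriers, a share of 29.5% (exact binomial p = 1.64e-05). No offspring carried 4 of these 14 regions, and a false call in a parent lowers the share. So does the carrier threshold: the region of chromosome 8 from 102122727 counts as carried by 2 of 8. Offspring 6 and 7 had 0.2499 and 0.23 there, against 0.26 in the dam. The p assumes that chromosomes are independent, whereas 4 of the 14 regions had one and the same set of carriers, the dam and offspring 5 to 8, so it is not a reliable measure of chance. With calls that held without their most extreme probe it was 35.7% (p = 0.044, exact binomial), and with a score of at least 10 it was 40% (p = 0.0929, exact binomial).

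Regions carried by an offspring and by neither parent were the changes the design sought. Of 85 regions with an offspring carrier and no parental carrier, 77 also differed from each parent by at least 0.25 in an offspring, as the rule for this count asked. Of the 77, 67 had a higher ratio, 70 had fewer than 10 probes and in 50 only 1 offspring met that rule. The 4 highest-scoring were carried by several offspring each. On chromosome 15 from 8344898 to 8367454, offspring 1, 2, 5, 6, 7 and 8 lay between -0.66 and -0.53, while the sire, dam and offspring 3 and 4 lay between -0.05 and 0.04. The same 6 offspring stood apart on chromosome 7 from 133217428 to 133245332, on chromosome 12 from 56189969 to 56256271 and on chromosome 14 from 53424661 to 54386805. These 6 were the animals of scan days 2, 4 and 5, and over the 4 regions the signal of the reference channel differed between those days and scan days 1 and 3 by more than 2 SD of random intervals, while that of the animal channel did not. Among regions of 1 offspring, offspring 7 had -0.68 ± 0.43 (SE) on chromosome 13 from 96524697 to 96533158, and -0.29 there without its most extreme probe. Its arrays differed, with -1.15 when the animal was in Cy3 and -0.21 when it was in Cy5. The latter met the orientation criterion but was short of the 0.25 asked of the mean. Offspring 1 had 0.71 ± 0.53 (SE) on chromosome 1 from 97734157 to 97746586, and 0.19 without that probe. Offspring 1 had 1.25 there in Cy3 and 0.17 in Cy5, which also met the orientation criterion but was short of 0.25. The count of 77 fell to 21 with calls that held without 1 probe, to 38 without the calls of offspring 6 and to 24 without those of offspring 5 and 6.

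The offspring were also compared with the reference over 46711 autosomal windows of 50 kb, in place of genes. The fit fixed beforehand, limma with a trended prior variance, called 0 windows, and 1 window of at least 0.25 had an unadjusted p under 0.05. That 0 cannot be read as an absence of change. In the window of chromosome 4 from 78450001 to 78500000 the 8 offspring had -0.35 ± 0.04 (SD, n = 8), yet the trended prior SD there was 3.68 and limma's adjusted p was 0.906. When known changes were added to the measured windows, that fit recovered 0% of changes of 0.4 and of 0.58 and 8% of changes of -1, although it recovered 100% of changes of -0.4. A constant prior, chosen after the data were seen, recovered 100% of each size and called 4 windows, 1 higher and 3 lower. The changes were added to all 8 offspring in windows with small ratios in every animal, so recovery in variable windows is not known. With that prior the window of chromosome 2 from 70050001 to 70100000 had a mean of 0.54 and a limma adjusted p of 0.0907. The window of chromosome 4 then had a limma adjusted p of 3.09e-11 and was lower in 8 of 8 offspring. Each p against the reference rests on 8 siblings and 1 reference male, whose own spread is left out of the test. It therefore reflects the spread among siblings and not 8 independent differences from the reference. The window of chromosome 2 from 177750001 to 177800000 was also called, with 0.26 and an adjusted p of 0.0407 by limma. It was higher in 6 of 8 offspring, while offspring 1 and 5 had -0.06 and -0.03. It lay inside a region carried by the sire, who had 0.42 in this window. The other windows called were a pair on chromosome 14 from 53650001 to 53750000, with -0.28 and -0.34 and adjusted p of 0.0097 and 0.0257 by limma. This pair lay inside the region that followed the scan days. With a robust constant prior 1 window was called.

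Offspring and parents did not differ past the threshold in any window. Limma called 0 of 46711 windows with the trended prior, where 2196 had an unadjusted p under 0.05, and 0 with the constant prior, where 2151 did. The trended fit recovered 0% of changes of 0.4, 0.58 and -1 added to the measured windows and 100% of changes of -0.4, and the constant fit recovered 100% of each size. These changes were added to all 8 offspring at once, so recovery of changes in only some offspring is not known. The region of chromosome 15 from 8344898, with 6 offspring between -0.66 and -0.53, gave no called window. The 0 is thus no evidence against changes in single offspring. Both parents were scanned on scan day 1 and no offspring was, so no scan day held both generations. With scan day as a random block, added after the data were seen, limma called 0 windows with either prior, and 2193 and 2147 had an unadjusted p under 0.05. Each of these unadjusted counts is under a share of 0.05 of the windows, the share that no difference would give.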

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

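The tests on scan-day splits, on the dam's regions, on offspring 6 and on single probes were chosen after the result was seen; those on the separate channels were fixed before. Among 25 sets of 8 offspring values, 2 had 1 offspring far from the others. Chance gives about 1 in 20 sets picked without regard to their values, but 21 of these sets were regions named for their scores or carriers, so that rate does not apply. Offspring 1 stood apart on chromosome 1 from 97734157, with a gap of 0.65 of the range, and offspring 7 on chromosome 13 from 96524697, with 0.716. Each rested largely on 1 array: with the animal in Cy5 offspring 1 had 0.17 and offspring 7 had -0.21, against 1.25 and -1.15 in Cy3.

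In 9 regions the 6 offspring of scan days 2, 4 and 5 stood apart from both parents and offspring 3 and 4 by at least 0.1, and the most regions parted by any of the 9 other ways to divide the 5 scan days 3 to 2 was 0. A median of 69.97% of the ratio difference lay in the reference channel and 30.0% in the animal channel, which argues against a copy number difference of the offspring themselves as the main part. This is consistent with a different reference DNA on those scan days. It rests on the longer regions: the reference share was 72.2% to 117% in the 4 regions of over 10 probes, and 5 of 9 regions passed 2 SD of random intervals. In the short regions of chromosome 3 near 113 Mb and chromosome 19 the animal channel held more, so those stay open.

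In 5 regions on 4 chromosomes the carriers were the dam and offspring 5 to 8 alone, which independent transmission would give on few chromosomes. The lowest X log2 ratio among these carriers was 0.90 and the highest among the other animals 0.02, so sequence shared with a sex chromosome is a candidate explanation. Of the 5, all but the region of chromosome 3 near 25 Mb lost the 0.25 threshold without 1 probe. The region of chromosome 8 from 102122727, with 47 probes, parted the animals in the same way, with 0.23 to 0.28 in the dam and offspring 5 to 8 and -0.03 to 0.03 in the others, although offspring 6 and 7 lay just under the carrier threshold.

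In 39 short regions called in offspring 6 alone with higher ratios, offspring 5 of the same scan day had a median of 0.22, which argues against gains of offspring 6 alone. Across windows without calls, which are not independent, the ratios of offspring 5 and 6 correlated at 0.502, and the highest pair from different scan days, offspring 5 and 8, at 0.403. The other pairs of one scan day had -0.09 (offspring 1 and 2), -0.28 (3 and 4) and 0.21 (7 and 8), so whether the pattern shared by offspring 5 and 6 came from their scan day cannot be told apart from other sources. No biological explanation was tested.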

How the results depend on the processing

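For calls and regions, the settings without an animal and without 1 probe were chosen after seeing the data, as were the constant prior and the scan days; leaving out animals in the planned window fits was not. Calls in the 8 offspring, 157 as reported, were 839 at a score of 6, 73 at 10, 348 with 3 probes, 85 with 10 probes, 65 without offspring 5 and 6 and 75 without each call's most extreme probe, and ran from 97 to 157 with 1 animal left out. Calls in the parents, 32, became 157, 13, 80 and 11 under the same score and probe settings, 20 without dim probes and 11 without the extreme probe, and ran from 13 to 32. Distinct regions, 121, became 849, 29, 327 and 34, then 58 with normexp, 74 without dim probes, 60 without offspring 5 and 6 and 35 without the extreme probe, and ran from 77 to 120. Regions of an offspring and neither parent, 77, became 547, 13, 218 and 17, then 32 with normexp, 38 at a mean of 0.4, 39 at a difference of 0.4, 47 without dim probes, 24 without offspring 5 and 6 and 21 without the extreme probe, and ran from 38 to 77; without the regions parting scan days there were 68. The lowest offspring calls and the lowest of both region counts were without offspring 6. The pooled share of carriers stayed under 50% in every setting run and lost its threshold at a score of 10, with 40%. For calls and regions, leaving out an animal dropped its calls, so the call counts fell by exactly those calls and test nothing further. A parent left out was still read for the regions of an offspring and neither parent. Any animal left out was still read for the pooled share. Those settings thus do not show that count without a parent or that share without that animal. The sire's Y ratio was 0.16 and -0.11 in the single orientations. Windows against the reference, 0 as planned, were also 0 with no size threshold, 4 with a constant prior, 1 with a robust one, 15 with a constant prior and no size threshold together, and 6 in scan days 2, 4 and 5 alone; the 4 ran from 1 to 8 with an offspring left out. Against the parents all settings gave 0. Of 105 values of 21 named regions under other signals, 100 lay within 1 probe SD, which is wide for the short regions, and 4 moved further. In all, 7 values of 5 regions fell under 0.25 in size. Chromosome 1 from 48266126 in offspring 6 went from 0.51 to 0.13 with normexp and 0.07 without dim probes, chromosome 10 from 52268364 in offspring 5 from 0.50 to 0.08 and 0.09, and chromosome 14 from 53424661 in offspring 5 from -0.27 to -0.21 with normexp. Chromosome 13 from 96524697 in offspring 7 went from -0.68 to -0.37 with normexp. The 4 were the region of chromosome 2 near 70 Mb in offspring 5, from 3.88 to 0.61 with normexp and 0.17 without dim probes, and with normexp chromosome 4 near 78 Mb in the sire, to -0.87, and chromosome 11 near 47 Mb in offspring 5, to -0.73. In addition 1 changed sign: chromosome 11 from 3031505 in offspring 5 was -0.024 with the running median removed. That region begins at the first probe of its chromosome, where the running median was padded with copies of that probe's value. This change of sign is therefore no test of the region. Apart from the probe, scan-day and prior tests, the cause was not tested. A random scan-day block against the parents, added after seeing the data, gave 0 with either prior; a fixed scan-day term was confounded with generation, and the gene lists were not run. No paired analysis was run, because all 8 offspring have the same sire and dam, so no offspring is matched to parents of its own.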

Other observations

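The copy-level test of chromosome 4 was chosen after the result was seen. Over the region from 78453216 to 78509511 the mean of the 8 offspring was -0.40 ± 0.04 (SD, n = 8), and 4 copies in the reference and dam with 2 in the sire would give -0.42 in every offspring and -1 in the sire, who had -1.01. With normexp the offspring had -0.38 ± 0.05 (SD, n = 8) and the sire -0.87 ± 0.07 (SE). A candidate explanation for 8 of 8 carriers is thus a sire with the lower copy level on both chromosomes, a hypothesis from the same data.

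Over the region of chromosome 2 near 70 Mb the reference channel lay at percentile 0.00778 of all probes, and the animal channel of the high-ratio animals at percentile 15.7. The size of the ratio is not settled there, with 0.61 in offspring 5 under normexp. This may reflect sequence missing from the reference male and present in the sire. The dam and offspring 4, 6 and 8 had 0.02, -0.24, 0.30 and 0.19 there, so the animals of the family also differ among themselves.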
